A study of Mus musculus with 48 samples.

How the data were processed

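Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in 48 libraries from 24 mouse ER-Hoxb8 clones. ER-Hoxb8 cells are bone marrow myeloid progenitors kept in an immature, dividing state by a Hoxb8 protein that is active only while oestrogen is present. Each clone gave 1 progenitor library and 1 monocyte library, and the series design states that the libraries are clonally paired. The clone number therefore pairs the samples, because both libraries of a number come from the same clone. No clone was measured more than 1 time per stage. P-values of tests over libraries or clones therefore measure the spread between clones, which includes the technical spread between libraries. Tests of calls by chromosome or 1-Mb window, and the Poisson test of regions private to a clone, took regions as units. Their p-values do not measure that spread.

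The deposited files are peak lists, 1 per library, in mm9 coordinates per the labels' protocols and processing notes. BWA is named in the submitters' processing notes, without a version. The peak caller, the read filters and any shift of reads for the transposase are not given in the sources used here. Each peak carries a pair of scores from the authors, and both deposited score columns have no header. The first score fell on an evenly spaced ladder in each list. Values below 40 steps lay within 0.1 step of a whole multiple for 91.0% to 100% of peaks per library, so 1 step was read as 1 tag. If all lists were scaled to one total, that reading gives the relative depth of the libraries, but not their totals. Neither that scaling nor the meaning of the second score is given in the sources used here. Scores served mainly to rank, filter or describe peaks within a list. Between lists they gave the relative depth, a cut at the pooled median score in an alternative for peak number, and library measures for adjusting the pairing. Other comparisons rest on presence or absence of peaks and on ranks within a list. Shares of a list's summed score are given for chromosome 17 and the mitochondrial sequence.

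Peaks were counted per library, and mean log10 peak numbers were compared by a two-sided permutation test with 100000 resamples. Positions in lists of unequal length cannot be compared directly, so lists were cut to one length before any comparison of positions. Every library with at least 10000 peaks was cut to its 10000 peaks of highest first score, which kept 42 libraries (24 progenitor and 18 monocyte) and left out the monocyte libraries of clones 15, 17, 19, 22, 23 and 24. Cut lists were merged where peaks overlapped by at least 1 bp, and regions held by at least 5 libraries were tested with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment at 0.05. Presence here means being among the 10000 highest peaks of a library. A region missing from a cut list can still be a lower peak of that library, and its count in the lists as deposited is given beside it.

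For clonal pairing, presence in each of the 18 clones with both libraries was centred on the frequency of its stage and on the library mean. The mean progenitor to monocyte correlation of same-clone pairs minus that of other-clone pairs was tested one-sided by permuting clone numbers 100000 times. Single regions were tested with Fisher's exact test of progenitor against monocyte presence across clones, where at least 3 clones held and at least 3 lacked the region in each stage. Similarity within a stage was the mean pairwise Jaccard index (shared regions over all regions held by either library), tested by swapping stages within clones 100000 times. The share of peaks on each of 20 chromosomes was correlated between stages across clones with permutation p-values.

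Text names the 12 regions per direction past the threshold with the largest difference in the share of libraries, and the 10 regions with the smallest p across clones. The tests, this rule and the first set of alternatives were fixed before the data were examined. Alternatives were lists of 5000 and 20000 peaks, 1-kb bins, the clones with the commonest naming code, other rankings, library offsets on the lists as deposited, and fits blocked by clone. Others were added after seeing the data: clones 1 to 13 only, clones 15 to 25 only, merging across 500 bp, leaving out libraries that stand apart, and adjusting the pairing for library measures. A naming code in the submitters' names of the progenitor lists and a break in the monocyte libraries between clones 1 to 13 and 15 to 25 served as possible batches.

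The region test was tested on simulated data drawn from the observed frequencies, with 200 changed regions. For the progenitor and monocyte comparison it recovered 0% of differences of 30 percentage points, 52% of those of 50 points and 98% of those of 70 points, among 13286, 13256 and 13287 regions. False calls numbered 0, 3 and 1. The data gave 3421 calls, which makes the adjusted threshold looser than with 200 changed regions. Some regions with a difference of 27.8 points passed there, so these shares do not give the recovery in the real comparison. For clonal pairing over 13781 regions, 8 of 100 simulated data sets with no shared regions passed 0.05, and 100 of 100 passed when 5% of regions were copied within clones. Each region was drawn independently in each library there, without the variation that regions of real libraries have in common. These pairing shares therefore do not give the power or the share of regions shared in the real data. For regions shared within clones, 200 of 200 copied regions were recovered among 2930 tested. These were copied exactly in every clone and planted together, which loosens the adjusted threshold. The recovery therefore does not give the power to find a single shared region.

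No mm9 gene annotation or genome was used here, so regions are given by position and the planned work on gene lists, distance to gene starts and motifs was not run. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.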

Results

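Open chromatin was profiled in 24 clones of ER-Hoxb8 myeloid cells, each as progenitors and as monocytes. The design asks how the chromatin of the stages differs and whether a clone's monocytes keep features of that clone's own progenitors. Progenitor lists held 79737 ± 30444 peaks (SD, n = 24; range 11114 to 136322) and monocyte lists 18930 ± 10791 (SD, n = 24; range 231 to 38786). The lowest peak kept in the lists of 10000 held 12 to 604 tags in progenitor libraries and 9 to 74 in monocyte libraries, so ranks near that boundary rest on few tags in the thinnest libraries. It held at most 19 tags in 7 monocyte libraries (clones 3, 10, 16, 18, 20, 21 and 25) and in 3 progenitor libraries (clones 11, 21 and 25).

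Progenitor lists held more peaks than monocyte lists in 23 of 24 clones. The ratio of geometric means was 5.17, and the p of 1e-05 is the smallest that 100000 permutations can give (two-sided). Swapping stages within clones gave the same p. Clone 11 was the exception, with 11114 progenitor and 24607 monocyte peaks. Among clones 1 to 13 the ratio was 2.65 (permutation p = 3e-05), a split added after seeing the data. Covered length was 7.72 ± 2.88 Mb in progenitors and 2.70 ± 1.48 Mb in monocytes (SD, n = 24 each), at mean peak widths of 98.3 and 147.8 bp. Peaks within a list had nearly 1 common width, so width describes the list and covered length follows peak number. Relative depth, set to 1 at the median library, was 2.17 ± 0.985 in progenitors and 0.748 ± 0.218 in monocytes (SD, n = 24 each), and the progenitor library was the deeper one in 22 of 24 clones. The exceptions were clones 21 (0.129 in progenitors, 0.775 in monocytes) and 25 (0.0894 and 1.43), whose progenitor lists were still the longer ones (33185 against 17591 and 22332 against 15260 peaks). The relation of log10 peak number to log10 depth was computed in 5 sets of libraries. In the 18 progenitor libraries with the commonest naming code it gave r = 0.0353 (permutation p = 0.844, adjusted p = 0.844) and rho = -0.0402 (permutation p = 0.876, adjusted p = 0.876), and r = -0.0597 without the 2 farthest libraries. In the monocytes of clones 1 to 13 it gave r = 0.0621 (permutation p = 0.800, adjusted p = 0.844) and rho = 0.0604 (permutation p = 0.849, adjusted p = 0.876), and r = 0.456 without the 2 farthest. In the 11 monocyte libraries of clones 15 to 25 it gave r = 0.894 (permutation p = 0.00383, adjusted p = 0.0163) and rho = 0.582 (permutation p = 0.0638, adjusted p = 0.106), and r = 0.735 without the 2 farthest. Taken whole, the 24 progenitor libraries gave r = 0.579 (permutation p = 0.00978, adjusted p = 0.0163) and rho = 0.455 (permutation p = 0.0259, adjusted p = 0.0826), and the 24 monocyte libraries gave r = 0.662 (permutation p = 0.00826, adjusted p = 0.0163) and rho = 0.440 (permutation p = 0.0330, adjusted p = 0.0826). Without the 2 farthest libraries r was 0.280 and 0.255, so both rest on few libraries.

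**Figure D1:**
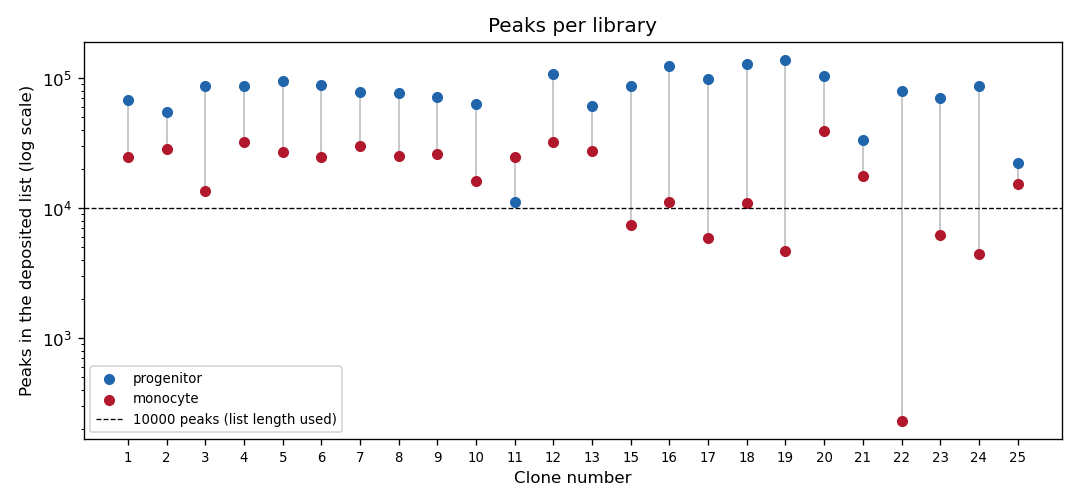
Peaks in each deposited list on a log scale, by clone number, with progenitor and monocyte libraries of a clone joined by a grey line and the list length of 10000 dashed. Progenitor points lie above monocyte points in 23 of 24 clones, and 6 monocyte libraries lie below the dashed line.

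Regions that ranked among the highest peaks in one stage and not the other were found in both directions. The 42 cut lists merged into 35237 regions, of which 13781 were held by at least 5 libraries and 1965 by all 42. Of the tested regions, 1588 (11.5%) were higher in monocytes and 1833 (13.3%) were higher in progenitors (Fisher's exact test, Benjamini-Hochberg adjusted p below 0.05), and 10360 passed in neither direction. The median difference was 47.2 percentage points of libraries for regions higher in monocytes, and -50.0 points, monocytes minus progenitors, for regions higher in progenitors. With clones as blocks (exact sign test over 18 clone pairs), 674 and 879 regions passed.

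The monocyte-higher regions were mostly peaks that progenitors also held at lower rank. Of the 1588, 752 were in no progenitor list of 10000, but only 7 were in no progenitor list as deposited, and the median region was a peak in 23 of the 24 deposited progenitor lists. Progenitor-higher regions were missing from all monocyte lists of 10000 in 635 cases and from all monocyte lists as deposited in 113 cases, with a median of 12 of 24 deposited lists. Monocyte lists are shorter, so absence from them is weaker evidence than absence from progenitor lists.

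The largest monocyte-higher difference lay on chromosome 15 at 59205619 to 59205927, among the highest peaks of 18 of 18 monocyte and 1 of 24 progenitor libraries (adjusted p = 4.06e-08). It did not pass with lists of 20000 peaks (adjusted p = 0.761), with library offsets (adjusted p = 0.894) or ranked by the second score (adjusted p = 0.400). A region on chromosome 7 at 29062621 to 29062981 followed with 18 of 18 and 2 of 24 (adjusted p = 2.12e-07). On chromosome 11, regions at 22872819 to 22873075 and 77500793 to 77501213 were each held by 16 of 18 monocyte and 0 of 24 progenitor libraries (adjusted p = 3.17e-07). Of the 12 named monocyte-higher regions, only the region at 77500793 was called again with lists of 20000 and with library offsets. In the lists as deposited, the 4 regions were peaks in 24, 23, 23 and 14 of 24 progenitor libraries. Regions on chromosome 2 at 33286543 to 33287139, chromosome 4 at 131901350 to 131901744, chromosome 9 at 59387334 to 59387593, chromosome 13 at 93544922 to 93545168 and chromosome 19 at 56622935 to 56623330 were held by 16 of 18 monocyte and 1 of 24 progenitor libraries. A region on chromosome 6 at 49299949 to 49300173 was held by 15 of 18 and 0 of 24. The remaining pair of named regions, on chromosome 11 at 50024106 to 50024403 and on chromosome 7 at 19857040 to 19857355, had a progenitor peak in the region or within 500 bp in 24 and 16 of 24 progenitor libraries.

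Among the named progenitor-higher regions, 4 had no monocyte peak within 500 bp in any cut list. They lay on chromosome 1 at 174443175 to 174443349, chromosome 9 at 20447666 to 20447811, chromosome 13 at 43356720 to 43356933 and chromosome 14 at 20796182 to 20796376. Each was held by 23 of 24 progenitor and 0 of 18 monocyte libraries (adjusted p = 4.06e-08), and each was a peak in 10 to 13 of the 24 monocyte lists as deposited. With library offsets 0 of these 4 passed (smallest adjusted p = 0.384). The other 8 had a monocyte peak within 500 bp in 12 to 18 of 18 monocyte libraries. That neighbour was also held by 22 to 24 of 24 progenitor libraries, and 21 to 24 held both, so the progenitor lists had an additional peak beside one that both stages held. These include the 3 regions with the largest difference, each held by 24 of 24 progenitor and 0 of 18 monocyte libraries (adjusted p = 1.3e-08). In 1-kb bins these 3 differed by -5.56 points (adjusted p = 0.642), so they depend on how positions are divided. They lay on chromosome 2 at 172196345 to 172196529, chromosome 5 at 129525477 to 129525623 and chromosome 8 at 72273825 to 72273991. The rest lay on chromosome 3 at 108003735 to 108003892, chromosome 9 at 21350608 to 21350754, chromosome 10 at 80755913 to 80756046, chromosome 11 at 6344058 to 6344223 and chromosome 13 at 112587329 to 112587470.

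Over all progenitor-higher regions, 799 of 1833 had a monocyte peak in the region itself or within 500 bp in at least 50% of monocyte libraries, and merging across 500 bp left 1197 progenitor-higher regions and 1464 monocyte-higher regions. Of the 799, 257 were called again after merging, which joins a region to its neighbour by construction, against 953 of the other 1034. The regions called also depended on how the lists were cut. Of the 1588 monocyte-higher regions, 185 were called in the same direction with lists of 5000 peaks and 444 with lists of 20000, and of the 1833 progenitor-higher regions 354 and 785 were. Only 286 of the 1588 and 645 of the 1833 overlapped a region tested with lists of 5000, against 1545 and 1833 with lists of 20000. With library offsets on the lists as deposited, 299 of the 1588 and 128 of the 1833 were, and ranked by the second score 511 and 921 were. At most 8 regions of either direction were called in the opposite one in any of these, with 7 monocyte-higher and 6 progenitor-higher regions when ranked by the second score.

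**Figure D2:**
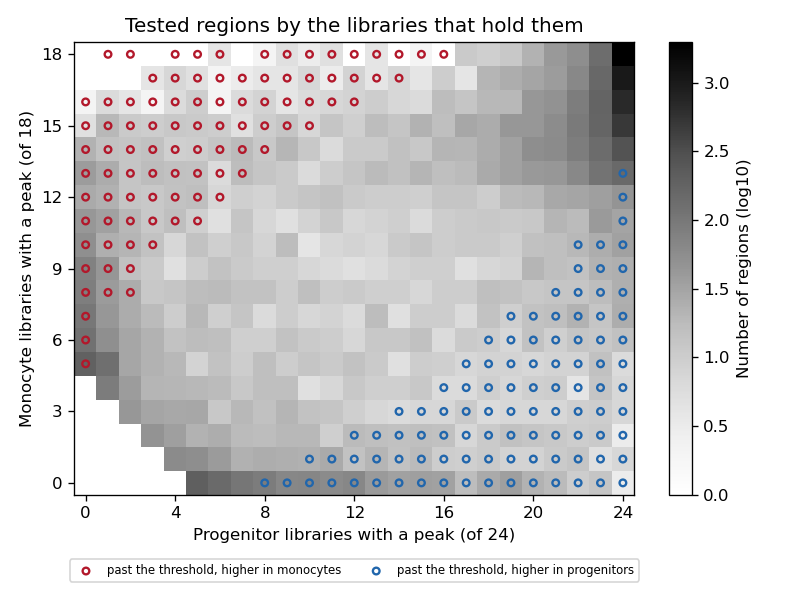
Each tested region is placed by the number of progenitor libraries (x axis, of 24) and monocyte libraries (y axis, of 18) that hold it among their 10000 highest peaks, with grey for the number of regions on a log10 scale. Circles mark combinations past the threshold, 1588 regions higher in monocytes and 1833 higher in progenitors, and the darkest corner holds the 1965 regions found in all 42 libraries.

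The monocytes of a clone resembled the progenitors of the same clone slightly more than those of other clones. Over 18 clones and 13781 regions, the correlation of centred presence was 0.0482 ± 0.0635 for same-clone pairs (SD, n = 18) and -0.0021 ± 0.0697 for other-clone pairs (SD, 306 pairs). The excess was 0.0503 (one-sided permutation p = 0.00199). It was p = 0.00085 when clone numbers were permuted only within the naming code and 0.0456 (permutation p = 0.00361) within clones 1 to 13. In the 5 other clones it was 0.0241 (exact permutation p = 0.117, one-sided, where 120 re-pairings allow 0.00833). The excess was small against the spread between pairs. The progenitors' best match was the monocytes of the same clone in 4 of 18 clones, where chance gives 1, and 14 of 18 same-clone correlations were positive. Clone 7 had the highest same-clone correlation (0.170) and clone 20 the lowest (-0.0818).

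The same-clone excess depended on how variation between libraries was adjusted for. Removing the first principal component of each stage, which held 22% of progenitor and 22.8% of monocyte variance, left an excess of 0.0034 (permutation p = 0.381) over 18 clones, and 0.0240 (permutation p = 0.0254) when repeated within clones 1 to 13. Over 18 clones, removing the first 2 left 0.0174 (permutation p = 0.00814), and adjusting for the median second score of each library left 0.0158 (permutation p = 0.131). Adjusting for tags at the lowest peak kept or for peak width left 0.0391 and 0.0434 (permutation p = 0.00418 and 0.00537). These adjustments were added after seeing the data. With the lists as deposited and library offsets the excess over 24 clones was 0.0080 (permutation p = 0.0736).

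**Figure D3:**
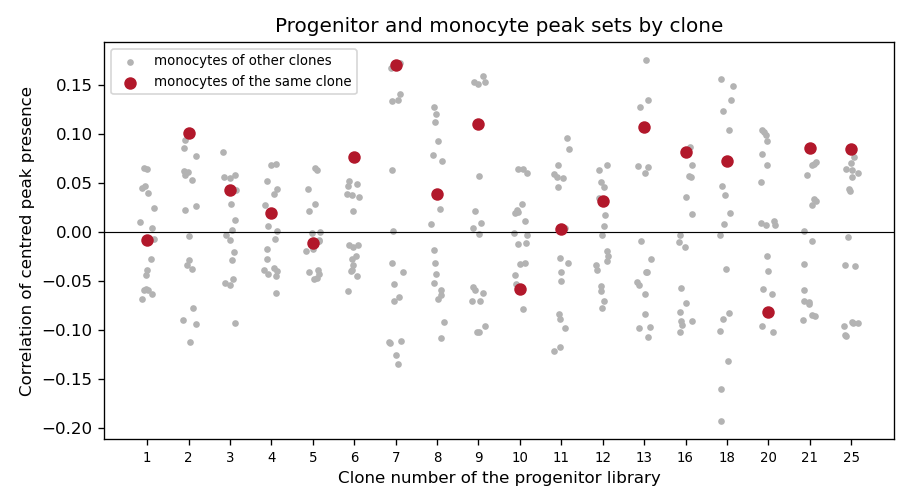
Correlation of centred peak presence (y axis) between each progenitor library (x axis, by clone number) and the monocyte libraries of the same clone (red) or of other clones (grey). Same-clone points average 0.0482 and other-clone points -0.0021, and the grey points of most clones extend above the red one.

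No single region passed the test for presence going together within clones. Of 3082 regions tested, 0 passed (Fisher's exact test, smallest Benjamini-Hochberg adjusted p = 0.166). The 3 regions that matched in all 18 clones were among those that failed (adjusted p = 0.166 and 0.336). With 18 clones even a full match is too weak to pass alone among 3082 regions. The 0 therefore does not speak against sharing of single regions. An unadjusted p below 0.05 was reached by 168 regions. In 99 re-pairings of clones that number was 68.8 ± 24.7 (SD), at most 162. In 137 of the 168 regions, presence went together more often than the frequencies give. The smallest p (5.39e-05) belonged to a region on chromosome 5 at 36235869 to 36236128, held in both stages by 12 clones and in neither by 6. Regions on chromosome 4 at 133428873 to 133429143 and chromosome 1 at 146047695 to 146047913 also matched in all 18 clones, with 14 and 4 clones holding both (unadjusted p = 0.000327). Among the 10 regions with the smallest p, 9 went together and 1, on chromosome 19 at 43827823 to 43828022, was held by 8 progenitor and 8 monocyte libraries but by 0 clones in both. The 6 others lay on chromosome 3 at 51456763 to 51456962, chromosome 13 at 112853930 to 112854251 and 72766029 to 72766258, chromosome 1 at 155261330 to 155261609, and chromosome 11 at 96685435 to 96685638 and 110198882 to 110199149.

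The similarity of clones to one another did not differ between stages past the threshold with lists of 10000 peaks. Over 18 clones, the mean Jaccard index was 0.704 ± 0.091 among progenitor libraries and 0.579 ± 0.225 among monocyte libraries (SD, 153 pairs each). The difference of 0.125 did not pass the test (two-sided permutation of stage within clones, p = 0.0707). It passed with lists of 5000 (0.119, permutation p = 0.0371) and of 20000 (0.129, permutation p = 0.0351), and was 0.0179 (permutation p = 0.893) in clones with the commonest naming code. Within clones 1 to 13 alone, a set chosen after seeing the data, the difference was -0.0391 (permutation p = 0.136). All 5 later monocyte libraries, of clones 16, 18, 20, 21 and 25, lay lower, with mean indices of 0.289, 0.531, 0.233, 0.333 and 0.450 to the other monocyte libraries, against 0.607 to 0.682 for clones 1 to 13. Without clones 16, 20 and 21 the difference was 0.0073 (permutation p = 0.843).

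A clone's share of peaks on a chromosome did not go together between its stages in a way that passed the test with lists of 10000 peaks. Of 20 chromosomes, 0 passed with Pearson's r (smallest adjusted p = 0.174) or Spearman's rho (smallest adjusted p = 0.242), and 2 and 4 had an unadjusted permutation p below 0.05. By Pearson's r these were chromosome 6 (r = -0.612, rho = -0.544) and chromosome 3 (r = -0.524, rho = -0.0547), which turned to r = 0.236 without the 2 farthest clones. By rho they were chromosome 6 and, with positive values, chromosomes 7, 18 and 19 (rho = 0.474, 0.493 and 0.506). With lists of 5000 peaks 5 chromosomes passed, 4 of them positive (7, 8, 13 and 19, r = 0.614 to 0.706), and with the commonest naming code 2 passed, both positive. Clone 9 held the highest progenitor share of peaks on chromosome 17, 6.68% against 5.22% ± 0.403 over all 24 progenitor libraries (SD), and its monocytes held 6.16% against 5.55% ± 0.937 (SD, n = 18), second to the 9.16% of clone 25. The correlation for chromosome 17 was r = -0.119 (permutation p = 0.393) and rho = -0.337 (permutation p = 0.172), and r = -0.541 without the 2 clones farthest on the progenitor axis.

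Ranks within the lists gave a measure less tied to the boundary at 10000, chosen after seeing the shares. In 3084 regions on these chromosomes that were peaks in all 42 of these libraries' lists as deposited, each region was ranked by score within its library and set against the stage median. The 157 regions on chromosome 17 were shifted by 22.6 percentile points in the progenitors of clone 9 and by 15.3 in its monocytes (median). The 192 regions on chromosome 1 were shifted by 17.8, 14.6 and 8.54 points in the progenitors of clones 13, 6 and 1, and by 0.126, -0.409 and -0.588 in the monocytes of these clones. The 37 regions on chromosome X were shifted by 17.3, 10.2 and 9.58 points in the progenitors of clones 16, 12 and 21.

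**Figure D4:**
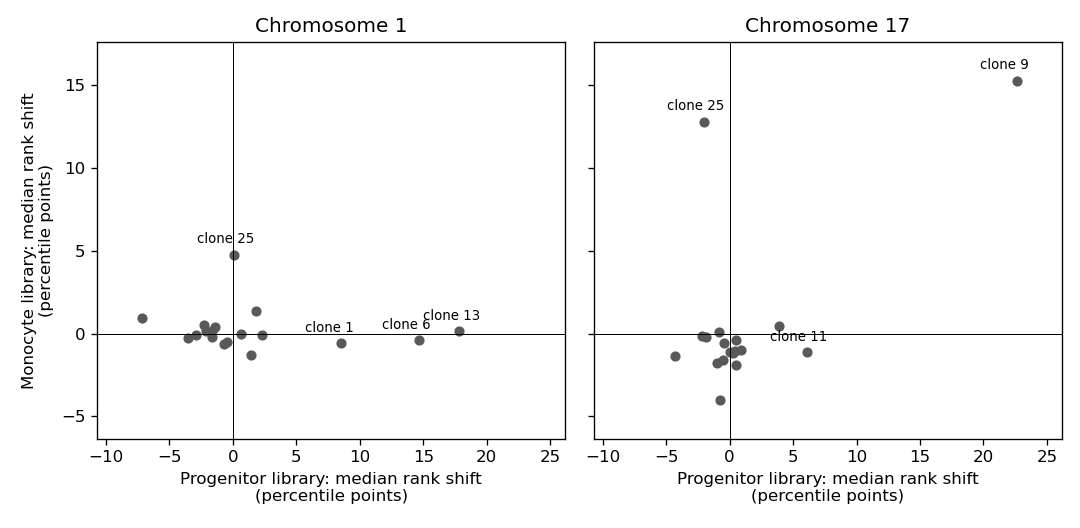
Median rank shift of the regions on chromosomes 1 and 17, in percentile points against the stage median, for the progenitor (x axis) and monocyte (y axis) library of each of 18 clones. Clone 9 lies high on both axes for chromosome 17 (22.6 and 15.3), clones 13, 6 and 1 lie high on the progenitor axis only for chromosome 1, and clone 25 lies high on the monocyte axis.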

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

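The tests of regions private to a clone, of chromosome 17, of library sets, of the 12 adjusted pairings, of re-pairings and of neighbouring regions were chosen after the results were seen. Centring per chromosome was planned, but its bound was set after its value was seen. The signal below lies in peaks under rank 10000, outside the main comparisons of positions. In the lists as deposited, 8 regions were held by the progenitor and the monocyte list of clone 13 and by no other list, against 0.372 expected from the numbers of such regions in each list (exact Poisson upper tail, adjusted p = 1.58e-07 over 24 clones). A pair of them lies on chromosome 10, at 41774135 to 41774266 and 41775122 to 41775276, and the highest lies on chromosome 11 at 97459678 to 97459811 with 117 progenitor and 27 monocyte tags. Those on chromosomes 1, 4 and X held 6 monocyte tags each, and that on chromosome 11 at 96166041 to 96166172 held 7. These lay at ranks 24003 to 25581 of 27534 monocyte peaks, near the end of the list. The Poisson tail takes regions as independent, so its p is too small where neighbours such as the pair go together. Over all clones, same-clone sharing of this kind was no more frequent than expected, at 115 regions against 123 (permutation p = 0.753). Clone 20 gave 60 of the 115, and without it there were 55 against 47.5 (permutation p = 0.235).

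The same-clone excess in peak presence was weighed against technical explanations. Chromosome gains as the whole cause are argued against by an excess of 0.0490 after centring each library per chromosome (permutation p = 0.00215). A shared naming code or library set is argued against by the permutation within these sets, p = 0.00217. Signal quality along the main axis of variation fits the result. Removing the first component of each stage left 0.0034 (permutation p = 0.381), past the bound of a fall to 50% of the excess. That axis may also carry a lasting difference between clones, and the test cannot separate these. Of 12 adjusted versions, 5 fell below 50% of the unadjusted excess of the same clones and 10 kept a permutation p under 0.05, 1 of them at 0.0490. They are the same adjustments run over 18 clones and again within clones 1 to 13, so they are not 12 separate checks. Over 18 clones, removing the first component or the first 2 left 6.74% and 34.5%. Adjusting for the second score, alone or with tags, left 31.4% and 43.8%, and for tags or peak width alone 77.7% and 86.4%. Within clones 1 to 13 the range was 44.9% to 76.0%. Progenitor chromatin in the monocyte libraries cannot be told apart from clonal memory here, because the share of progenitor-higher regions in a monocyte library and its same-clone correlation gave rho = 0.418 (permutation p = 0.155) and r = 0.444 (permutation p = 0.128) over clones 1 to 13, and r = 0.290 without the 2 farthest. The test was kept to these 13 clones after the 5 others were seen to hold far fewer such regions, 5.29% to 8.02% against 15.9% to 37.4%, and over all 18 rho was 0.228 (permutation p = 0.362).

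For the number of regions with an unadjusted p below 0.05 across clones, 1 of 100 re-pairings, the real one included, gave as many as 168. The highest other gave 162. This count was chosen after the results were seen, so chance is not firmly excluded. For the 137 of them that went together, 2 of 100 gave as many, and the highest other equalled the real value. For the stage comparison, 1 of 100 splits gave as many calls as the real 3421 and the highest other gave 0. With clones as blocks, 1 of 100 swaps gave as many as the real 1553 and the highest other gave 0. Chance is excluded for both.

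The stage differences were weighed against peak position and width. The nearly common width of a list was 120 to 204 bp in monocyte and 86 to 130 bp in progenitor libraries. Regions with a peak of the other stage in the region or within 500 bp made up 43.6% of progenitor-higher and 7.56% of monocyte-higher regions. Such a peak was counted where at least 50% of the other stage's libraries held one. These shares argue against peak position as the whole cause. They do not decide on width, which could change the ranks of peaks without leaving a nearby peak in the other stage's cut lists. The width ranges of the stages barely overlap, and an effect of width on ranks was not tested. Among progenitor-higher regions, 502 had a neighbouring region within 500 bp that at least 50% of monocyte libraries held. For these a peak shifted in position is argued against, because at least 50% of progenitor libraries also held that neighbour in 97.6% of cases. How nearby peaks were divided in each stage remains open for them, since merging joins such pairs by construction. The monocyte libraries of clones 16, 20 and 21 do not carry the result alone: without them, 93.6% of monocyte-higher and 70.9% of progenitor-higher regions were called again. Depth as the whole cause is argued against by clones 21 and 25, whose progenitor libraries are shallower than their monocyte libraries. This holds only if the lists were scaled to one total, as the reading of depth assumes. With regions called from the other clones, the progenitor libraries of clones 21 and 25 held 56.4 and 40.3 points more of the progenitor-higher than of the monocyte-higher regions. Both lay at least 46.8 points above the highest monocyte library, that of clone 20 at -6.43. The progenitor library of clone 11, deep (2.04) but with 16 tags at the lowest peak kept, lay lowest among progenitors at 18.3. Monocyte libraries with few such tags were divided. Those of clones 3, 10, 16, 20 and 21 lay at -16.9 to -6.43, and those of clones 18 and 25 at -64.0 and -53.9. Tags at the boundary, as opposed to depth, were not tested as a cause.

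The chromosome 17 shift in clone 9 was weighed against a few changed peaks, and 100% of its 10-Mb windows lay above the stage median in both libraries. List length and depth are argued against by a shift at least 5.57 times that of the next autosome in the same library. The share of summed score on chromosome 17 was 1.50 times the stage median in progenitors and 1.52 times in monocytes, within 0.0590 of what 1 extra copy in a diploid cell gives. That gap lies inside the spread of the ratio between libraries (SD 0.170 over 24 progenitor and 0.207 over 18 monocyte libraries). A candidate explanation is an extra copy of chromosome 17 that clone 9 carried before it matured, which remains a hypothesis found and tested on the same data. No group of the design bears on it.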

How the results depend on the processing

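Alternatives named as added were chosen after seeing the data. The peak number ratio kept its direction and significance in every alternative run. Pairing kept both except with library offsets (0.0080, p = 0.0736) and in added adjustments: without the first component of each stage (0.0034, p = 0.381) and adjusted for the median second score (0.0158, p = 0.131). In clones 15 to 25 (added, 5 clones) it gave 0.0241 (exact p = 0.117). Leaving out 1 clone gave 0.0431 to 0.0594, with p at most 0.00694.

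Regions higher in monocytes and in progenitors numbered 915 and 1111 with lists of 5000 and 3977 and 4257 with lists of 20000. They numbered 674 and 879 with clones as blocks (18 pairs), 2698 and 2932 ranked by the second score (32.2% and 50.2% of the main calls kept), and 965 and 777 in clones 1 to 13 (added, fewer libraries). Merging across 500 bp (added) left 1197 progenitor-higher regions. With library offsets on the lists as deposited there were 6277 and 2178, so that 74.2% of calls were monocyte-higher against 46.4% in the main test.

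Of the 24 named regions, 9 were called in the same direction with lists of 20000 and 6 with library offsets. In 1-kb bins 7 lost their call, 6 of them progenitor-higher. Over all alternatives, named regions lost their call with the same direction or no difference in 50 cases and turned direction without passing the threshold in 8. With offsets the differences were -0.126 points (chromosome 15), -0.711 (chromosomes 2 and 9), -2.53 (chromosome 4) and 0.51 (chromosome 1 at 174443175). With lists of 20000 the regions on chromosome 4 and on chromosome 7 at 19857040 gave -3.99, and with merging the region on chromosome 11 at 50024106 gave -11.1. The cause was not tested.

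The similarity difference passed with lists of 5000 (0.119, p = 0.0371) and 20000 (0.129, p = 0.0351). It also passed with stage labels permuted over all libraries, a larger set without the pairing block (0.149, p = 0.0353). It was 0.0179 (p = 0.893) with the commonest naming code and 0.0598 (p = 0.259) by shared base pairs, and reversed in clones 1 to 13 (-0.0391). Regions with an unadjusted p under 0.05 for sharing within clones numbered 78 and 75 with lists of 5000 and 20000, 42 with the commonest naming code and 106 with at least 5 clones with and without, where fewer regions were tested. Chromosome shares gave 5 calls with lists of 5000, 1 of them negative, and 2 with the commonest naming code. With Spearman's rho, 3 and 0 of these passed. The cause was not tested. Annotation, gene list and motif alternatives were not run, for want of an mm9 reference here. Few tags limit the ranks near the boundary in the 7 monocyte libraries whose last kept peak held 9 to 19 tags.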

Other observations

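The tests in this part were chosen after seeing the data. Stage differences were unevenly spread over chromosomes, with 5 of 40 tests of chromosome and direction passing (Fisher's exact test, Benjamini-Hochberg). On chromosome 11, 14.3% of tested regions were monocyte-higher against 11.3% elsewhere (adjusted p = 0.0230), and 9.72% were progenitor-higher against 13.6% elsewhere (adjusted p = 0.00242). Chromosome 7 held fewer monocyte-higher regions, 7.81% against 11.8% (adjusted p = 0.00242). Progenitor-higher regions were fewer on chromosome 19, 8.28% against 13.5% (adjusted p = 0.0103), and more frequent on chromosome 18, 18.9% against 13.2% (adjusted p = 0.0230). Neighbouring regions are not independent, so these p-values are too small where calls come in clusters.

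Progenitor-higher regions lay within 100 kb of another such region in 40.9% of cases, above all 1000 random draws of as many tested regions (mean 35.8%, highest 39.9%). Monocyte-higher regions did so in 35.0% of cases, within the range of the random draws (mean 32.2%, highest 36.9%). No 1-Mb window passed a test for an excess of calls (smallest adjusted p = 0.490 for progenitor-higher and 0.242 for monocyte-higher regions).

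The monocytes of clone 25 had 9.16% of their peaks on chromosome 17 and 8.50% on chromosome 1, the highest of the 18 monocyte libraries for both, with rank shifts of 12.8 and 4.73 percentile points. The progenitors of clone 25 had shifts of -2.03 and 0.0567. The summed score of the monocytes on chromosome 17 was 0.975 times the stage median, against 1.52 times in clone 9. Mitochondrial peaks took 64.5% and 53.4% of the summed score in the monocyte libraries of clones 3 and 10, against a median of 4.50% over the 24 monocyte libraries.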
